A study of Caulobacter vibrioides with 12 samples.

How the data were processed

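Total RNA of wild-type Caulobacter crescentus NA1000, a bacterium whose motile swarmer cells become stalked cells and then divide asymmetrically, was profiled in synchronized cultures at 3 stages of the cell cycle. The stages were swarmer cells, stalked cells taken 45 min after synchrony and predivisional cells taken 90 min after synchrony, all in M2G minimal medium. At each stage RNA was taken at 0, 1, 3 and 9 min of rifampicin at 100 µg/mL, an antibiotic that blocks the start of transcription. This gives 12 libraries, 1 for each stage and time. The treatment protocol in the labels lists other minutes than the sample titles and the design text; the times in the titles are used here. Per the labels' protocols, ribosomal RNA was removed with a kit, tRNA was left in as a stable internal control, and libraries were made by adapter ligation, circularization and PCR.

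The authors deposited 1 table with raw read counts per gene and library, the counts per the file headers being whole numbers. The same table gives RPKM values made by the authors, named so per the file headers. In 99.97% of the values the RPKM length was the gene length minus 1 base, within a tolerance of 0.1%. Reads were aligned with Bowtie 0.12.8 per the submitters' processing notes. The read counter, the genome build, the handling of reads with several matches and the use of strand are not given in the sources used here. Counts of near-identical genes, such as the flagellin genes, and of overlapping or antisense genes are therefore uncertain.

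The table holds 3936 features. Of these, 3885 matched a locus tag in the gene table of assembly ASM2200v1, Caulobacter vibrioides NA1000, which was used for names and for neighbouring genes alone, and 665 had a symbol of their own. The other 51 were taken as tRNA genes from their identifiers, and 4 of those had 0 reads in every library. Other genes are given by locus tag.

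Each library was scaled so that the median ratio of 40 tRNA genes, those with at least 100 reads in every library, to the 0 min library of the same stage was 1. The 0 min libraries of the 3 stages were set against each other by their total counts, most of which are tRNA. A level is therefore a level relative to total reads, and an overall change of mRNA against tRNA between stages enters it. Scaled counts are given at a common depth of 18934383 reads. Genes were kept where the mean count of the 3 libraries at 0 min was at least 10, which left 3794 genes outside the tRNA set.

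Half-lives came from a least-squares line through the natural log of the scaled count plus 1 over the 4 times. A half-life above 30 min, or a slope of 0 or more, was called not resolved. Its standard error comes from the scatter of 4 points about the line. Within a stage there is no test.

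Differences between stages were tested on counts with edgeR quasi-likelihood (edgeR 4.0.16, R 4.3.3) over all 12 libraries, with stage, rifampicin time as a factor and stage by minutes in the model, and Benjamini-Hochberg adjustment with a threshold of 0.05. The stage-by-minutes terms give differences of decay in log2 per min, and the stage terms give differences of level at 0 min in log2. The spread came from departures from a curve shared by the stages, with 4 residual degrees of freedom and 4.93 prior degrees of freedom, and the biological coefficient of variation was 29.1%. No stage and time was repeated, and the 4 times of a stage may come from 1 culture, so the p-values do not cover differences between cultures. Standard errors were taken from the estimate and its F statistic. The comparison of RPKM at 0 min counts genes at least 4-fold apart on the log2(RPKM + 1) scale, as a description with no test; that scale understates changes of low genes.

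Gene lists were matched by symbol. They covered cell cycle regulators (30 members found), division and cell wall (22), flagellum (44), chemotaxis (14), pili and holdfast (24), stalk and surface layer (7), ribosomal proteins (26), translation factors (7), RNA decay (5), transcription (13), DNA replication and repair (19), chaperones and proteases (11), ATP synthase and respiration (21) and central carbon metabolism (9). In the translation list, 6 aminoacyl-tRNA synthetases were matched by symbols chosen after the gene table was read. A list of TonB-dependent receptors, meant to be found by product wording, was not analysed here, and rhlE was not analysed here. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 42 list tests each for decay and for level, and again with an estimated correlation. Camera compares a list with all other genes, so list medians are given relative to the median of all genes. The list half-lives were set among 10000 random lists of the same size matched on mean RPKM in 20 bins, as a description of these libraries.

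The groups, the tests, the lists, the alternative settings and the rule for named genes were chosen before the data were examined. The rule takes, per comparison and direction, the 5 genes with the largest difference past the threshold and a level of at least 50, the 5 shortest and 5 longest half-lives per stage with R squared of at least 0.9, a fixed set of regulators and RNA decay genes, and list members with the highest level or the largest called difference. There were 28 other settings of the model, some of them added after the data were seen, with other scalings, filters, tools and curve shapes and with each library left out in turn; DESeq2 1.42.0 was among the tools. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.

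The model was tested on simulated counts for stalked against swarmer cells over 3794 genes. Of 100 genes given a slope difference of 0.3 log2 per min it recovered 39%, and of 100 given 0.6 it recovered 76%. For level differences of 1 and 2 log2 it recovered 14% and 79%, and it called 3 of 3594 unchanged genes. The counts were drawn gene by gene from the fitted model, so no library as a whole departed from it. These rates do not cover such departures in the real libraries. The half-life step, tested on simulated genes starting at 200 reads, returned a median of 1.21 min for a true half-life of 1 min and 4.00 min for 4 min. For 8 min the median was 8.34 min, with 5th and 95th percentiles of 5.06 and 21.5 min. Single long half-lives are therefore uncertain. The simulated genes followed a single exponential curve, with a spread that was set and not taken from these libraries. The half-life simulation thus does not cover genes that level off late, other curve shapes or errors of scaling. Intervals and floors given for few reads cover counting error only, since PCR reads without molecular identifiers are not independent molecules.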

Results

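The loss of mRNA after rifampicin was followed in swarmer, stalked and predivisional cells, with 4 libraries per stage at 0, 1, 3 and 9 min and 1 library for each stage and time. Total counts ran from 6490665 to 33433048 reads. The lowest was the stalked library at 0 min and the highest the predivisional library at 9 min. Most reads were tRNA. At 0 min the tRNA share was 85.2% in swarmer, 86.2% in stalked and 83.2% in predivisional cells, and at 9 min it was 96.0%, 98.5% and 96.6%. The widest 95% Wilson interval of a tRNA share spanned 0.0531 percentage points. The mRNA and other non-tRNA reads were therefore few: 2683924 in swarmer, 898595 in stalked and 2682834 in predivisional cells at 0 min, and 677647, 250513 and 1152087 at 9 min. In the stalked library at 9 min the median gene had 7 reads and 406 genes had 0 reads, against 33 reads and 71 genes in swarmer and 63 reads and 48 genes in predivisional cells.

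After scaling by tRNA, non-tRNA reads fell at all 3 stages. At 1 min 47.6% of the 0 min total was left in swarmer, 57.1% in stalked and 66.7% in predivisional cells, and at 3 min 28.3%, 36.9% and 32.6%. Between 3 and 9 min the stages parted. At 9 min 24.8% was left in swarmer, 9.96% in stalked and 18.2% in predivisional cells. Per gene, the median left at 9 min was 11.9%, 2.86% and 9.61%.

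**Figure D1:**
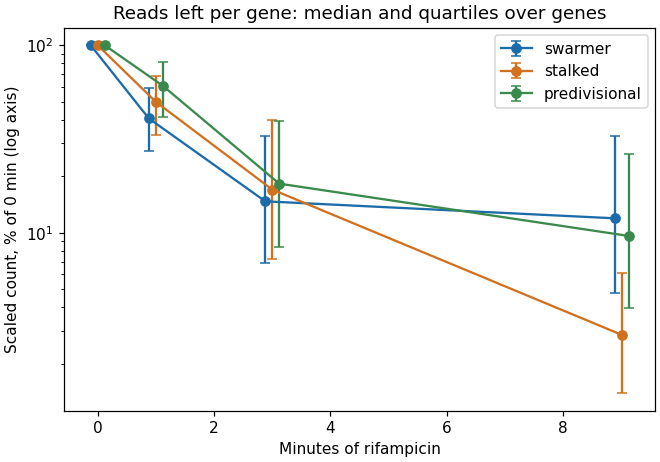
Scaled count of each gene as a percent of its 0 min value (log axis) against minutes of rifampicin, with a line for the median over genes and capped bars for the quartiles, 1 library per point. At 9 min the median is 2.86% in stalked cells, below 11.9% in swarmer and 9.61% in predivisional cells.

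The mRNA of dnaA, which encodes the initiator of chromosome replication, had a half-life of 1.54 min (SE 0.537) in swarmer, 1.39 min (0.418) in stalked and 1.58 min (0.536) in predivisional cells. That of ctrA, which encodes a response regulator that controls many cell cycle genes and blocks replication initiation, had 3.88 min (2.53), 1.71 min (0.581) and 1.24 min (0.252). In predivisional cells ctrA was among the 5 shortest half-lives with an R squared of at least 0.9. The mRNA of gcrA, a regulator active around replication, had half-lives of 2.34 min (0.456), 2.88 min (0.309) and 3.38 min (0.185). For ccrM, which encodes a DNA methyltransferase, none was resolved in swarmer cells, and it was 4.43 min (1.25) in stalked and 2.54 min (1.56) in predivisional cells. For rne, the gene of the endonuclease RNase E, half-lives were 1.74, 1.85 and 1.66 min, and for pnp, the gene of polynucleotide phosphorylase, 4.85, 2.32 and 2.89 min. The standard errors come from 4 points per stage, and no time was repeated.

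At the ends of the range stood other genes. Short half-lives in swarmer cells included panD, whose product makes beta-alanine for coenzyme A, at 1.27 min (SE 0.256) and phd at 1.31 min. In stalked cells they included thiS, a sulfur carrier of thiamine synthesis, at 1.12 min and CCNA_02206 at 1.12 min. In these stages phd, thiS and CCNA_02206 had 0 reads at 9 min, so those values depend on the added count of 1. In predivisional cells CCNA_03858 had 1.21 min and ctrA 1.24 min. CCNA_02309 was among the 5 longest at every stage, with 10.4 min (0.457) in swarmer, 12.8 min (2.10) in stalked and 19.7 min (3.64) in predivisional cells. In stalked cells nuoM, a subunit gene of respiratory complex I, had 10.9 min (2.31). In predivisional cells CCNA_01231 had 29.1 min (2.52) and CCNA_01035 16.7 min (0.593).

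Over all 3794 genes, the median half-life was 3.53 min in swarmer, 1.99 min in stalked and 3.01 min in predivisional cells. Half-lives were not resolved for 559, 35 and 316 genes. A straight line described part of the genes only, with an R squared of at least 0.9 in 15.0%, 47.6% and 25.6%. The medians depended on the times used. Without the 9 min library of each stage they were 1.14, 1.24 and 1.24 min, and without the 0 min library of each stage 5.65, 2.31 and 4.08 min.

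Median half-lives of functional groups were set beside those of random lists, as a description. Flagellum genes had a median half-life of 5.19 min in swarmer and 3.31 min in stalked cells, above at least 99.97% of random lists matched on mean RPKM over the 3 stages, and 1.87 min in predivisional cells, below every random list drawn. The match does not cover the level within a stage: the median RPKM of these genes at 0 min was 6.40, 2.90 and 45.03, so the longer half-lives go with low levels. In stalked cells the half-lives of members such as flgD, with 2 reads at 0 min, and flgL, with 3, depend on the added count of 1. Without the 9 min libraries the flagellum medians were 1.42, 1.43 and 0.780 min, at percentiles 99.09, 96.77 and 0. Pilus and holdfast genes had 7.37, 2.60 and 2.19 min, and chemotaxis genes 3.38, 2.75 and 2.05 min. Ribosomal protein genes had 2.64, 1.78 and 1.71 min over 9 min. Over the first 3 min alone they stood out as slow, with 3.13 min in swarmer and 7.15 min in predivisional cells and no resolved loss in stalked cells, at percentiles 98.88, 100 and 100. Genes of ATP synthase and respiration also lost little over 0 to 3 min, with medians of 5.22, 11.6 and 3.62 min at percentiles 99.96, 100 and 99.84. Chemotaxis genes had 3.49, 2.72 and 6.73 min over that time. Cell cycle regulators were on the fast side over 0 to 3 min, with 0.890, 0.890 and 0.850 min at percentiles 10.1, 3.66 and 1.40. Over 9 min they were not, at percentiles 49.0, 17.9 and 75.1.

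The following groups had shorter medians over 9 min than flagellum genes in swarmer and stalked cells. In swarmer, stalked and predivisional cells, division and cell wall genes had 3.18, 1.76 and 1.95 min, DNA replication and repair genes 3.22, 1.77 and 2.67 min, and stalk and surface layer genes 4.19, 1.58 and 2.18 min. Chaperones and proteases had 2.03, 1.74 and 2.35 min, transcription genes 1.92, 1.71 and 1.93 min, and RNA decay genes 1.95, 1.85 and 1.84 min. Translation factors had 2.38, 1.49 and 2.07 min and central carbon genes 2.03, 1.68 and 1.73 min. Regulators of the cell cycle had 2.63, 1.76 and 2.52 min, and ATP synthase and respiration genes 3.54, 1.89 and 2.71 min.

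Fitted half-lives were shorter for genes with a higher level at 0 min. Spearman's rho between half-life and RPKM at 0 min was -0.52 in swarmer, -0.39 in stalked and -0.52 in predivisional cells, over 3235, 3759 and 3478 genes, and Pearson's r on log2 values was -0.46, -0.25 and -0.43. Genes are not independent replicates and no p-value is given. The 0 min library gives both the level and the first point of the line, so its noise alone pushes rho below 0. With the level of another stage rho was -0.42, -0.32 and -0.46. Few reads at late times can also lengthen the fitted half-lives of low genes, and the size of that effect was not tested. With half-lives over 0 to 3 min rho was -0.26, -0.26 and -0.22. In stalked cells it was -0.17 with 0.1 added to each count in place of 1, and -0.61 with 5.

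Levels before rifampicin were compared between stages. In all comparisons of level and of decay, stage cannot be told apart from time since synchrony. From swarmer to stalked cells, some genes of DNA replication, division and the stalk were higher and some of motility and pili lower. By the edgeR model, ftsZ, which encodes the tubulin-like division ring protein, was higher in stalked cells by 4.83 log2 (SE 0.42, adjusted p = 0.000112), with a scaled count of 11173 against 428. The division-site regulator gene mipZ was higher by 4.26 (0.30, adjusted p = 6.41e-05), gcrA by 3.75 (0.26, adjusted p = 6.41e-05) and podJ, a polar localization factor, by 3.94 (0.35, adjusted p = 0.000127). Lower in stalked cells were sciP, which encodes a small inhibitor of CtrA, by -4.11 (0.38, adjusted p = 0.000153), rcdA, an adaptor for CtrA proteolysis, by -3.95 (0.31, adjusted p = 7.71e-05) and the pilin gene pilA by -2.88 (0.22, adjusted p = 7.71e-05), with 3509 against 23666. The ctrA mRNA was higher by 1.94 (0.26, adjusted p = 0.000884). For dnaA the difference was -0.92 (0.21, adjusted p = 0.0118), and adjusted p was 0.138 without the stalked library at 0 min, 0.0717 without stalked 1 min and 0.0802 without swarmer 0 min. Of the fixed regulators, ccrM (adjusted p = 0.697), divK (0.576) and popZ (0.132) did not pass.

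**Figure D2:**
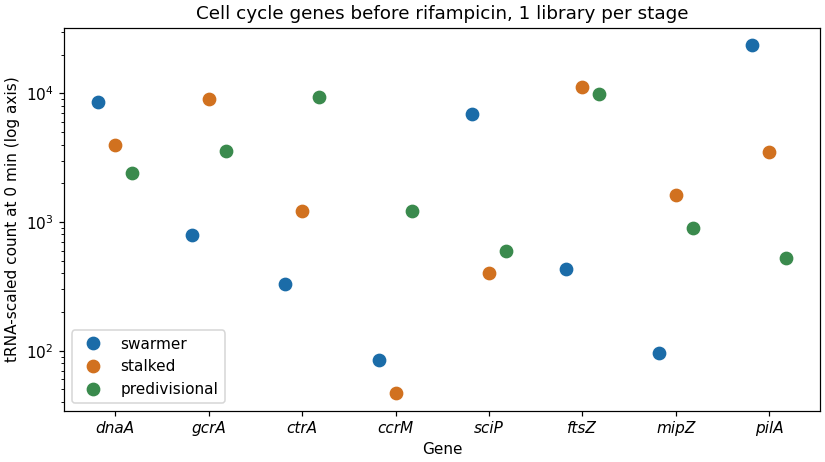
Scaled count at 0 min of rifampicin (log axis) of 8 cell cycle genes in swarmer, stalked and predivisional cells, 1 library per point. The ctrA value goes from 331 to 1216 and 9369 across the stages, and pilA from 23666 to 3509 and 524.

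The largest increases in stalked cells by the rule were CCNA_03325 at 5.45 (SE 0.32), stpC, a stalk protein gene, at 5.33 (0.54), CCNA_01178 at 5.25 (0.50), cysH, a gene of sulfate assimilation, at 5.13 (0.30), and dgcA at 4.95 (0.43). The largest decreases were CCNA_03906 at -6.27 (0.48), CCNA_03327 at -4.82 (0.32) and zerB at -4.80 (0.33). All of these had an adjusted p of 0.000209 or less in the edgeR model. CCNA_02286 had 0 reads in the stalked library at 0 min and 106 in swarmer, a scaled level at least 12.7-fold higher in swarmer against a floor of 3 counts in that library. Its adjusted p was 0.00708, and 0.0503 without the stalked library at 0 min. CCNA_01606 had an adjusted p of 0.0192, and of 0.101 and 0.0718 without the stalked libraries at 0 and 1 min.

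Gene groups moved as follows from swarmer to stalked cells, with list medians relative to the median of all genes. Of 44 flagellum genes, 17 fell and 2 rose, with a relative median of -1.40, and adjusted over the list alone 21 fell and 2 rose. The flagellin genes fljK and fljM fell by 3.16 (SE 0.25) and 3.15 (0.24). For flgD, a hook assembly gene, the 0 min libraries held 2 reads in stalked against 125 in swarmer cells, a scaled ratio of 22.6 with an exact 95% interval from 6.1 to 188. Of 24 pilus and holdfast genes, 11 fell and 2 rose (relative median -1.42; adjusted over the list alone, 12 and 2). Among them hfsJ fell by 3.96 (0.41) and hfsE by 2.96 (0.32), while hfsB rose by 3.04 (0.34). Of 14 chemotaxis genes 2 fell (relative median -1.15; adjusted over the list alone, 4), with cheYI at -2.28 (0.30). By camera, adjusted p was 1.82e-06 for flagellum, 0.000299 for pili and holdfast and 0.00335 for chemotaxis. For each of these 3 lists adjusted p = 0.397 with an estimated correlation.

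In the other direction, 18 of 26 ribosomal protein genes rose from swarmer to stalked cells and none fell (relative median 1.38; adjusted over the list alone, 20), with rplE at 2.09 (SE 0.27) and rpsQ at 2.14 (0.30). The genes rpsM and rpsK did not pass, at 0.12 and 0.05. Of 7 stalk and surface layer genes, 4 rose (relative median 1.83; adjusted over the list alone, 4), with stpA at 4.84 (0.38) and stpB at 4.54 (0.35). The surface layer gene rsaA was at 0.46 and did not pass. Of 19 genes of DNA replication and repair, 8 rose (relative median 0.57; adjusted over the list alone, 8), including recA, the recombinase gene, at 2.39 (0.32), dnaE, a polymerase subunit gene, at 1.88 (0.29), and nrdJ, a ribonucleotide reductase gene, at 1.64 (0.26). Adjusted p by camera was 8.38e-07 for ribosomal proteins and 7.73e-05 for the stalk list, both with adjusted p = 0.397 with an estimated correlation. For the replication list it was 0.00335, and adjusted p = 0.5 with an estimated correlation.

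Division and cell wall genes and genes of energy metabolism rose in part from swarmer to stalked cells. Of 22 division and cell wall genes, 6 rose (relative median 0.32; adjusted over the list alone, 7), with murD, a peptidoglycan precursor ligase gene, at 3.48 (SE 0.34) and creS, the crescentin gene that gives the cell its curve, at 2.22 (0.31). Adjusted p by camera was 0.0181, but 0.602 with an estimated correlation and 0.063 without the swarmer library at 0 min. Of 21 genes of ATP synthase and respiration, 11 rose and 3 fell (relative median 1.03; adjusted over the list alone, 12 and 3). The complex I gene nuoH rose by 2.50 (0.32), and the 3 that fell were ccoN, ccoO and ccoP of the cbb3 oxidase, a terminal oxidase with high affinity for oxygen, at -4.76 (0.53), -4.15 (0.57) and -4.42 (0.67). Adjusted p for the list was 0.0295, but 0.71 with an estimated correlation, 0.0584 without predivisional 0 min, 0.0883 without stalked 0 min and 0.11 without swarmer 0 min. Lists that did not pass were regulators (11 rose, 11 fell; adjusted over the list alone, 11 and 12), chaperones (0 and 3; alone, 0 and 3), transcription (1 and 2; alone, 1 and 2), central carbon (3 and 0; alone, 3 and 0), translation factors (0 and 0) and RNA decay (0 and 0). The heat-shock sigma factor gene rpoH fell by 2.39 (0.32).

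In all, 828 of 3794 genes differed in level between stalked and swarmer cells, 455 higher and 373 lower in stalked cells. Without the 9 min libraries 454 were higher and 628 lower, and the median of all genes was -0.16 in place of 0.10. A model with straight decay lines called 86 genes. The count was 452 without stalked 0 min, 444 without stalked 1 min and 504 without swarmer 1 min.

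**Figure D3:**
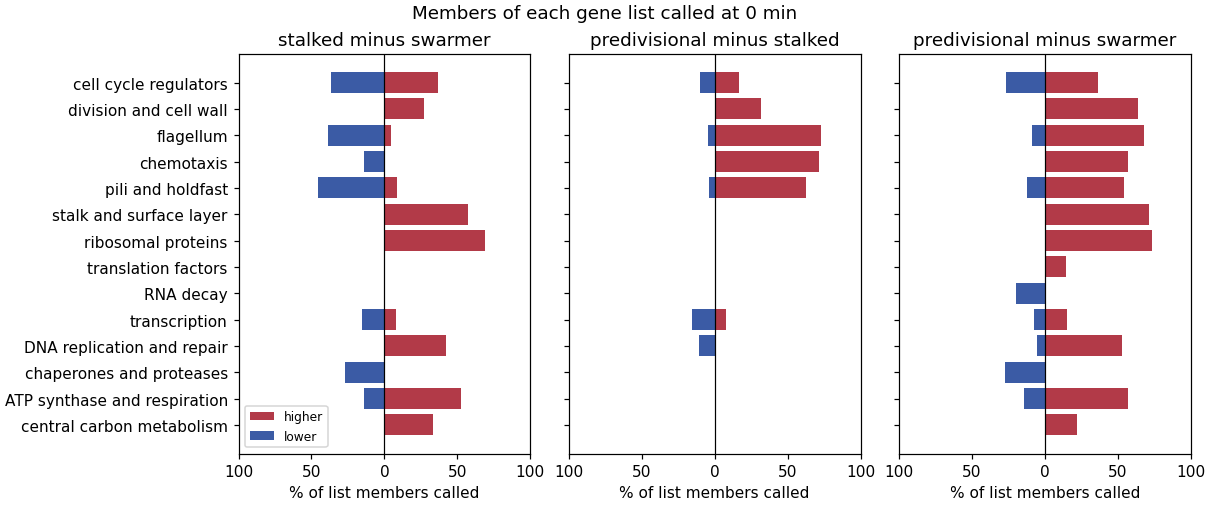
Percent of the members of each gene list called higher or lower at 0 min by edgeR quasi-likelihood, for stalked against swarmer, predivisional against stalked and predivisional against swarmer cells. Of 44 flagellum genes, 17 were lower and 2 higher in stalked than in swarmer cells, and 32 were higher and 2 lower in predivisional than in stalked cells, and the direction of their median was the same under each scaling run.

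From stalked to predivisional cells, many genes of the flagellum, chemotaxis and the pilus rose and a few fell. Of 44 flagellum genes, 32 rose and 2 fell (relative median 4.06; adjusted over the list alone, 35 and 3). The hook protein gene flgE rose by 6.08 (SE 0.39) and fliE, a basal body gene, by 5.98 (0.72). For flgD the 0 min libraries held 526 reads in predivisional and 2 in stalked cells, a scaled ratio of 108 with an exact 95% interval from 29.6 to 890, and its adjusted p was 6.72e-05 by edgeR. The flagellin genes parted: fljL rose by 4.10 (0.23), and fljN and fljM fell by 2.89 (0.27) and 2.03 (0.24). Of 14 chemotaxis genes 10 rose and none fell (relative median 2.81; adjusted over the list alone, 12), with cheYI at 4.29 (0.31) and the kinase gene cheAI at 3.72 (0.40). Of 24 pilus and holdfast genes, 15 rose and 1 fell (relative median 3.05; adjusted over the list alone, 20 and 1). The pilus assembly genes cpaG and cpaE rose by 5.86 (0.38) and 5.41 (0.39), and hfsA of holdfast synthesis by 5.30 (0.35), while pilA fell by 2.58 (0.22). Adjusted p by camera was 9.1e-52 for flagellum and 6.36e-28 for pili and holdfast, each with adjusted p = 0.131 with an estimated correlation, and 2.5e-21 for chemotaxis, with adjusted p = 0.0234 with an estimated correlation.

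Among regulators, ctrA rose by 3.17 (SE 0.27, adjusted p = 0.000256 by edgeR), from a scaled count of 1216 to 9369. The gene of the DNA methyltransferase CcrM rose by 4.07 (0.53, adjusted p = 0.00228) and ftsK, the DNA translocase gene of the division site, by 3.87 (0.48, adjusted p = 0.00166). The stalk regulator gene staR fell by 2.21 (0.25, adjusted p = 0.00124), and malA, which encodes an outer-membrane receptor for maltose, stood at -4.63 (0.33, adjusted p = 9.85e-05). For gcrA the difference was -1.20 (0.25, adjusted p = 0.023), and adjusted p was 0.25 without predivisional 0 min, 0.128 without predivisional 1 min, 0.159 without stalked 0 min, 0.175 without stalked 1 min and 0.0596 without swarmer 1 min. The levels of ftsZ at -0.27 (adjusted p = 0.854), dnaA at -0.71 (0.107) and mipZ at -0.94 (0.0866) did not pass. Of the 30 regulators 5 rose and 3 fell (adjusted over the list alone, 8 and 5), and the list did not pass (adjusted p = 0.69).

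Further genes at the top of the predivisional increase had few reads in stalked cells. CCNA_00945 had 432 reads against 1 at 0 min, a scaled ratio of 176 with an exact 95% interval from 31.5 to 6988, and an adjusted p of 0.000113 by edgeR. For flgC, a rod gene of the flagellum, reads were 572 against 3, a ratio of 77.0 (26.2 to 375), with an adjusted p of 0.00236 that was 1.0 without the stalked library at 0 min. CCNA_03944 had 0 reads in all 4 stalked libraries and 126 in predivisional cells at 0 min, a scaled level at least 17.1-fold higher against a floor of 3 counts in the 0 min library. Its adjusted p was 0.0166, and 0.131 without predivisional 0 min, 0.0648 without predivisional 1 min, 0.0537 without predivisional 9 min, 1.0 without stalked 0 min and 0.0505 without swarmer 1 min. At the other end, CCNA_02368 had -3.48 (SE 0.54, adjusted p = 0.00536), with 0.0516 without predivisional 1 min and 0.0584 without stalked 0 min.

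The remaining lists moved less between stalked and predivisional cells. Of 22 division and cell wall genes, 7 rose (adjusted over the list alone, 8), with adjusted p = 0.0062 by camera but 0.602 with an estimated correlation and 0.0661 without the stalked library at 9 min. Their median was 0.09 above that of all genes, and the median itself was 0.32 but negative with median-scaled libraries and with TMM. Of the replication and repair genes 0 rose and 2 fell (adjusted over the list alone, 1 and 3), and of transcription genes 1 rose and 2 fell. In the ribosomal protein, stalk, translation, RNA decay, chaperone, respiration and central carbon lists 0 genes passed in the edgeR test. Their list tests did not pass.

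In all, 205 genes differed in level between predivisional and stalked cells, 166 higher and 39 lower in predivisional cells, and the median of all genes was 0.23. The balance depended on the scaling. With median-scaled libraries the median of all genes was -0.20 and 153 genes were higher and 103 lower, with TMM 174 and 94, and with DESeq2 size factors 216 and 112. The count was 407 without the 9 min libraries and 24 with straight decay lines. Leaving out a library gave 118 without predivisional 0 min, 92 without predivisional 1 min, 130 without predivisional 9 min, 80 without stalked 0 min, 85 without stalked 1 min and 313 without stalked 9 min.

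Differences between predivisional and swarmer cells included ctrA, pilus genes and flagellins. By edgeR, ctrA was higher in predivisional cells by 5.11 log2 (SE 0.29, adjusted p = 1.89e-05), chpT, the phosphotransfer gene upstream of CtrA, by 3.82 (0.30, adjusted p = 4.65e-05), and ftsZ by 4.57 (0.41, adjusted p = 8.42e-05). The pilus genes cpaF and cpaG were higher by 5.69 (0.49) and 5.29 (0.34), and the flagellum genes flgC, fliE and fliO by 6.40 (0.55), 5.40 (0.64) and 5.31 (0.52). Lower were the flagellin genes fljN by -5.95 (0.30, adjusted p = 1.17e-05) and fljM by -5.17 (0.26), pilA by -5.45 (0.24) and staR by -5.60 (0.28), each at the same adjusted p as fljN. CCNA_03906 was lower by -6.44 (0.48), zerB by -5.32 (0.33), sciP by -2.76 (0.38, adjusted p = 0.00072) and dnaA by -1.63 (0.21, adjusted p = 0.000535). For ccrM the difference was 3.70 (0.48, adjusted p = 0.000593), for gcrA 2.56 (0.25, adjusted p = 0.000139) and for mipZ 3.32 (0.29, adjusted p = 7.74e-05). The kinase gene divJ did not pass (-0.06, adjusted p = 0.875), nor did rne (0.788) or pnp (0.0608).

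By group, 30 of 44 flagellum genes rose and 4 fell from swarmer to predivisional cells (relative median 2.40; adjusted over the list alone, 32 and 4), and 13 of 24 pilus and holdfast genes rose and 3 fell (1.92; alone, 14 and 4). Of 22 division and cell wall genes, 14 rose and none fell (1.03; alone, 16), with murD at 3.67 (SE 0.34) and ftsK at 3.35 (0.45). Of 26 ribosomal protein genes, 19 rose and none fell (1.19; alone, 21), with rplE at 2.36 (0.27) and rpsC at 2.29 (0.26). Of 7 stalk and surface layer genes, 5 rose (1.63; alone, 5), with stpA at 4.58 (0.37), and of 14 chemotaxis genes 8 rose (1.15; alone, 8), with cheWI at 2.99 (0.43). Adjusted p by camera was 2.28e-07 for flagellum, 0.00173 for pili, 7.62e-05 for division, 1.66e-05 for ribosomal proteins, 0.000617 for stalk and 0.0062 for chemotaxis. All 6 had adjusted p = 0.397 with an estimated correlation, and chemotaxis had 0.0729 without swarmer 0 min. Of 11 chaperones and proteases, 3 fell (relative median -0.75; alone, 3), with dnaJ, a co-chaperone gene, at -1.31 (0.25). For that list adjusted p was 0.0256, but 0.602 with an estimated correlation and 0.0584 without predivisional 0 min.

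Lists that did not pass between predivisional and swarmer cells were DNA replication and repair (10 rose, 1 fell; adjusted over the list alone, 10 and 1), respiration (12 and 3; alone, 12 and 3), regulators (11 and 8; alone, 12 and 8), transcription (2 and 1; alone, 2 and 1), central carbon (2 and 0; alone, 2 and 0), RNA decay (0 and 1; alone, 1 and 1) and translation factors (1 and 0; alone, 0 and 0). Within them recA rose by 2.69 (SE 0.32), nuoH by 2.48 (0.32) and sucB, a citric acid cycle gene, by 1.93 (0.30). The cbb3 oxidase genes ccoO and ccoN fell by 4.35 (0.53) and 3.30 (0.48), and rpoH fell by 2.27 (0.31).

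In all, 1051 genes differed between predivisional and swarmer cells, 752 higher and 299 lower in predivisional cells, and the median of all genes was 0.40. With median-scaled libraries, where that median was 0.01, 565 were higher and 550 lower. With TMM the numbers were 553 and 554, and with DESeq2 size factors 620 and 587. A model with straight decay lines called 150 genes. The count was 538 without predivisional 0 min, 603 without predivisional 1 min and 582 without swarmer 1 min.

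The deposited RPKM at 0 min alone, with 1 library per stage and no test, put 389 genes at least 4-fold apart between stalked and swarmer cells, 104 higher and 285 lower in stalked cells. That balance is opposite to the one of the model with all libraries, 455 higher and 373 lower. Without the 9 min libraries the model had the same balance as the RPKM, with 454 higher and 628 lower. The level at 0 min in the model thus moves with the 9 min libraries. Between predivisional and stalked cells 172 genes were 4-fold apart, 161 higher and 11 lower in predivisional cells, and between predivisional and swarmer cells 359, with 209 higher and 150 lower. With median-scaled libraries the numbers were 129 higher and 241 lower, 129 and 24, and 173 and 165.

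Decay was then compared between stages, which the half-life design was built for. Against swarmer cells, stalked cells lost ftsZ mRNA faster, with a slope difference of -0.65 log2 per min (SE 0.08, adjusted p = 0.00545 by edgeR). The same held for mipZ at -0.47 (0.07, adjusted p = 0.00583), the histidine kinase gene pleC at -0.49 (0.09, adjusted p = 0.0095) and ctrA at -0.33 (0.06, adjusted p = 0.00819). For flgD the difference was 0.59 (0.14, adjusted p = 0.0193), but it had 2 reads at 0 min and 2 at 9 min in stalked cells, too few to show a loss there. Among the 5 largest negative differences were CCNA_02407 at -1.36 (0.24, adjusted p = 0.00848) and CCNA_02901 at -1.19 (0.18, adjusted p = 0.00615). The first had 0 reads in stalked cells at 9 min, and both had more scaled reads at 9 than at 3 min in swarmer cells (28.8 against 5.2, and 3014.9 against 20.8), as did ftsZ (145.2 against 107.1). The decay of dnaA (-0.07, adjusted p = 0.243), gcrA (0.09, 0.23), sciP (0.12, 0.248) and rne (0.04, 0.697) did not pass. In all 1132 genes differed, 1112 with a more negative and 20 with a less negative slope in stalked cells, against a median of all genes of -0.19.

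These decay calls rested on the 9 min libraries and on the scaling, and a slope over 9 min, here and in the comparisons below, includes any rise between 3 and 9 min. Without the stalked 9 min library 0 genes were called by edgeR quasi-likelihood, with 222 at an unadjusted p under 0.05, and adjusted p was 0.638 for ftsZ, 0.782 for mipZ, pleC and flgD, 0.655 for ctrA, 0.743 for CCNA_02407 and 0.801 for CCNA_02901. Without the swarmer 9 min library 4 genes were called, and those values were 0.0982 for ftsZ and pleC, 0.256 for mipZ, 0.317 for flgD, 0.34 for ctrA, 0.327 for CCNA_02407 and 0.729 for CCNA_02901. The count was 676 without stalked 1 min and 559 without swarmer 1 min. Without all 3 libraries at 9 min 7 genes were called, with 540 at an unadjusted p under 0.05. With median-scaled libraries 321 genes were slower and 285 faster in stalked cells, with TMM 281 and 298, and with DESeq2 size factors 520 and 380.

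By list, DNA replication and repair genes had more negative slopes in stalked than in swarmer cells (0 slower and 13 faster of 19; adjusted over the list alone, 0 and 13), at -0.08 relative to all genes (camera adjusted p = 0.0123, and adjusted p = 0.591 with an estimated correlation). Members rose in swarmer cells between 3 and 9 min, such as gyrB from a scaled count of 233.0 to 810.4 and dnaE from 200.8 to 349.1, and over 0 to 3 min the list's median half-lives were 1.13 min in swarmer and 1.04 min in stalked cells. Flagellum genes passed in the other direction relative to all genes, by 0.10 (adjusted p = 0.0115, and adjusted p = 0.766 with an estimated correlation), though their own median and mean were below 0, at -0.10 and -0.15. Of those 44 genes, 2 were slower and 3 faster (adjusted over the list alone, 1 and 2). Neither list passed without the stalked 9 min library (0.147 for replication, 0.483 for flagellum) or the swarmer 9 min library (0.107 and 0.347, the latter with the direction turned). The other 12 lists did not pass.

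From stalked to predivisional cells, flagellum genes had more negative slopes relative to other genes, at a median RPKM of 2.90 in stalked cells at 0 min. Their median slope difference was -0.33 relative to all genes, with 4 of 44 called faster and none slower (adjusted over the list alone, 4). Among them were flgD at -0.54 (SE 0.12, adjusted p = 0.0404 by edgeR) and fliR, an export gate gene, at -0.46 (0.12, adjusted p = 0.0478), with 2 and 7 reads in stalked cells at 0 min. CCNA_00439 decayed faster at -0.41 (0.05, adjusted p = 0.0175), and CCNA_01041 had 1.76 (0.37, adjusted p = 0.0388), a size set by its stalked scaled counts of 0 at 3 and 9 min. For ctrA the difference was -0.22 (adjusted p = 0.0524) and for ftsZ 0.25 (adjusted p = 0.0675), and neither passed. Adjusted p by camera was 2.01e-11 for flagellum, 0.00018 for chemotaxis and for ribosomal proteins and 0.000247 for pili and holdfast, at -0.23, -0.15 and -0.16 relative to all genes for the latter 3. All 4 had adjusted p = 0.591 with an estimated correlation. In chemotaxis and ribosomal protein genes 0 members were called, and ribosomal protein genes had a median of -0.01 and a mean of 0 of their own. In pili and holdfast 1 was slower (adjusted over the list alone, 0 in each). Chemotaxis had 0.684 without predivisional 9 min and 0.564, with the direction turned, without stalked 9 min, and ribosomal proteins had 0.0531 without predivisional 9 min.

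In all 322 genes differed in decay between predivisional and stalked cells, 314 slower and 8 faster in predivisional cells, against a median of all genes of 0.14. With median-scaled libraries 110 were slower and 183 faster, with TMM 122 and 112, and with DESeq2 size factors 269 and 450. The edgeR count was 0 on leaving out predivisional 0, 1 or 9 min or stalked 1 or 9 min. None of the calls above outlasted these. Genes at an unadjusted p under 0.05 then numbered 850, 1181, 223, 1040 and 173. The median slope difference of all genes was then 0.13, 0.154, 0.095, 0.14 and -0.04, so it turned without stalked 9 min alone. The edgeR count was 80 without predivisional 3 min and 51 without swarmer 1 min. There flgD had an adjusted p of 0.0602 and 0.0724, fliR of 0.0682 and 0.0762, and CCNA_01041 of 0.0693 and 0.0688. Without stalked 0 min those 3 had 0.058, 0.0801 and 0.35. The count rose to 861 without stalked 3 min, 729 without swarmer 0 min, 657 without swarmer 3 min and 874 without swarmer 9 min. Without all libraries at 9 min it was 0, with 247 genes at an unadjusted p under 0.05, against 719 by DESeq2 with all libraries.

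Between predivisional and swarmer cells, ctrA mRNA decayed faster in predivisional cells by -0.55 log2 per min (SE 0.06, adjusted p = 0.0135 by edgeR). Less negative slopes in predivisional cells were those of hfsJ at 0.59 (0.08, adjusted p = 0.0142), cydA, an oxidase subunit gene, at 0.54 (0.08, adjusted p = 0.0142) and malA at 0.46 (0.07, adjusted p = 0.0142), all of which rose there between 3 and 9 min, from scaled counts of 39.9 to 92.1, 88.6 to 310.1 and 36.5 to 69.0. CCNA_00106 had -0.71 (0.09, adjusted p = 0.0135), but its scaled count rose from 93.6 at 3 min to 3155.9 at 9 min in swarmer cells, and over 0 to 3 min its half-lives were 1.15 min in swarmer and 1.00 min in predivisional cells. In all 113 genes differed, 100 faster and 13 slower in predivisional cells, against a median of all genes of -0.05. With median-scaled libraries 65 were slower and 111 faster, with TMM 67 and 99, and with DESeq2 size factors 161 and 198. Without predivisional 1 or 9 min or swarmer 1 min 0 genes were called by edgeR, with 555, 228 and 575 at an unadjusted p under 0.05. DESeq2 called 359 with all libraries. The median slope difference of all genes was -0.035, -0.088 and -0.039 in those edgeR fits. Without swarmer 9 min 13 were called, and adjusted p was 0.112 for ctrA, 0.187 for cydA, 0.207 for malA and 0.557 for CCNA_00106. Without predivisional 0 min 12 were called, and adjusted p was 0.06 for hfsJ and 0.0687 for cydA. The count was 31 without predivisional 3 min, 71 without stalked 0 min, 17 without stalked 1 min, 174 without stalked 3 min, 280 without stalked 9 min, 233 without swarmer 0 min and 215 without swarmer 3 min.

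Lists with more negative slopes in predivisional than in swarmer cells were pili and holdfast (1 slower and 8 faster of 24; adjusted over the list alone, 1 and 14), flagellum (0 and 7 of 44; alone, 0 and 16), division and cell wall (0 and 4 of 22; alone, 0 and 9), ribosomal proteins (0 and 2 of 26; alone, 0 and 11) and stalk and surface layer (0 and 1 of 7; alone, 0 and 6). Relative to all genes their medians were -0.28, -0.20, -0.13, -0.12 and -0.17 log2 per min. Adjusted p by camera was 9.18e-06, 3.83e-08, 0.000247, 0.000842 and 0.00425, and each had adjusted p = 0.591 with an estimated correlation. Without swarmer 9 min pili had 0.0771, ribosomal proteins 0.368 and the stalk list 0.176, and without predivisional 9 min ribosomal proteins had 0.17 and the stalk list 0.0936. For the lists that passed, in the order above, the median RPKM at 0 min in swarmer cells was 6.73, 6.40, 17.15, 137.57 and 6.24. In predivisional cells it was 37.75, 45.03, 50.59, 399.4 and 87.52, and an effect of these levels on the slopes was not tested. Over 0 to 3 min their median half-lives in swarmer cells were 1.87, 1.42, 0.99, 3.13 and 1.46 min. In predivisional cells they were 1.30, 0.78, 0.82, 7.15 and 1.23 min, so ribosomal protein genes went the other way. The other 9 lists did not pass.

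Over the 3 stages together, 846 genes differed in decay by the F test. The count was 30 without the 9 min libraries and 0 with straight decay lines, where 788, 549 and 127 genes had an unadjusted p under 0.05 in the pairs stalked and swarmer, predivisional and stalked, and predivisional and swarmer; DESeq2 with tRNA scaling called 1385 over the 3 stages. Leaving out a library gave 410 without predivisional 0 min, 340 without predivisional 1 min, 511 without predivisional 3 min, 291 without predivisional 9 min, 173 without stalked 1 min, 1299 without stalked 3 min, 100 without stalked 9 min and 203 without swarmer 1 min.

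Some genes had more scaled reads at 9 than at 3 min of rifampicin. In swarmer cells 486 genes were at least 2-fold higher at 9 min with a scaled count of at least 50, in predivisional cells 182 and in stalked cells 0, with no test. The gene smc, which encodes the chromosome-organizing SMC protein, had 3378 at 3 min and 12240 at 9 min in swarmer cells, with 42.7 in stalked and 9598 in predivisional cells at 9 min. CCNA_01924 went from 1635 to 34478 in swarmer cells, with 2.1 in stalked and 8439 in predivisional cells at 9 min.

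**Figure D4:**
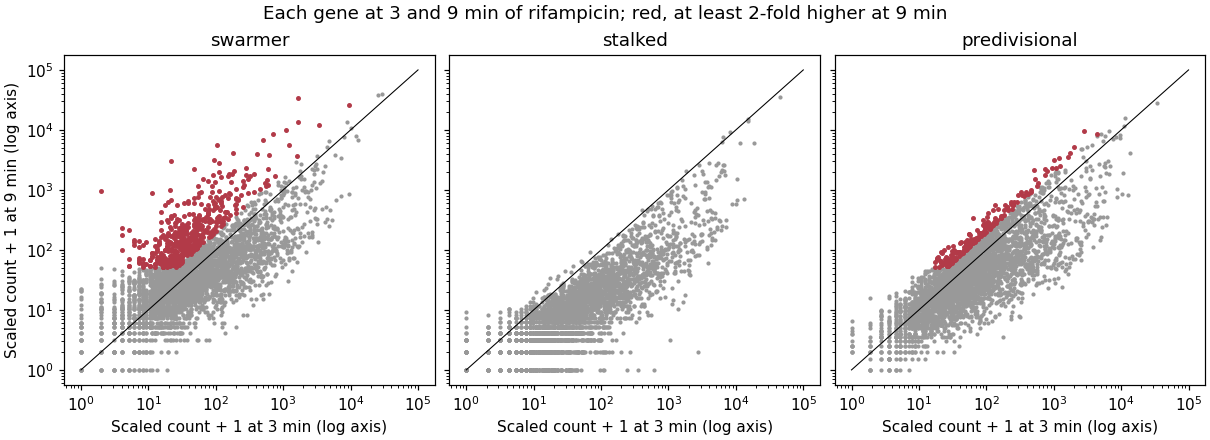
Scaled count plus 1 of each gene at 3 min (x) and 9 min (y) of rifampicin, log axes, 1 panel per stage. Red points are genes at least 2-fold higher at 9 min with a scaled count of at least 50: 486 in swarmer, 0 in stalked and 182 in predivisional cells.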

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

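The tests of explanations in this part and the exchanges of stage labels were chosen after the results had been seen; the comparisons between stages and the setting without the 9 min libraries were planned. The differences of decay between stages stood out because the model tested them directly: 846 genes differed over the 3 stages, 1132 between stalked and swarmer cells, 322 between predivisional and stalked cells and 113 between predivisional and swarmer cells, by edgeR quasi-likelihood with Benjamini-Hochberg adjustment.

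Of the 1132 genes, 1112 had a more negative slope in stalked cells. A library that stands apart at 9 min could carry this difference. The median slope difference of all genes was -0.19 log2 per min with the 9 min libraries and 0.039 without them, so the overall shift came with these libraries. A wrong scaling factor of 1 of them would move every gene alike. Among the 846 genes with a scaled count of at least 100 at 3 min, 27.2% moved by less than 0.5 of their own median shift of -0.92 (quartiles -1.90 and -0.40), but with 1 library per stage at 9 min this spread cannot be told apart from a spread between libraries, so such a factor stays open. With median-scaled libraries, which take out such a factor, 606 genes differed, 321 slower and 285 faster in stalked cells. Whether the stalked or swarmer cells or the 9 min samples themselves differ stays open, since each stage has 1 library at 9 min. Tested without the 3 libraries at 9 min, 7 genes differed between stalked and swarmer cells, 5 slower and 2 faster in stalked cells, with 540 at an unadjusted p under 0.05.

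Stage labels were exchanged within rifampicin times. For the 3 stages, 100 labellings out of 216 were used, the real one among them. Of these, 6 gave at least the real 846 genes, the real one included, and the highest other count was 1719. Labels at 0 min were kept, so an exchange at a later time lets level differences between stages enter the slopes. The exchanges therefore cannot tell whether the decay calls arose by chance. For each pair of stages there are 8 labellings, the real one included, too few for a share under 0.05. For decay the real and the highest other counts were 1132 and 1862 between stalked and swarmer, 322 and 1460 between predivisional and stalked, and 113 and 497 between predivisional and swarmer cells. For level they were 828 and 1093, 205 and 267, and 1051 and 999. For the pairs, the highest other count came from exchanging the 9 min libraries, and for decay between predivisional and stalked cells from exchanging those at 3 and 9 min. For decay, 3, 3 and 2 of the 8 labellings gave at least the real count in these pairs, the real one included. Between stalked and swarmer cells the median of the other exchanges was 531. The counts of 1460 and 497 are several times the real ones, while the median of the other exchanges was 0 in both of those comparisons. The late libraries are the ones exchanged there, and what sets these counts was not tested.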

How the results depend on the processing

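The robust edgeR fit, the limma settings, DESeq2 with tRNA scaling, the 10 RPKM filter and half-life against level over 0 to 3 min were chosen after the data were seen; the other settings were planned. The planned pseudocounts do not apply to a count model and were run in limma, and the setting without the variance trend was run in limma and in edgeR. Median scaling sets the overall decay to 0 and gives no half-life. No analysis paired by culture or replicate was possible because there is 1 library per stage and time and the labels give no replicate numbers. The model matched the stages on rifampicin time only. Few non-tRNA reads limit the stalked values, with 250513 at 9 min. The cause of the changes below was not tested, except that a left-out time gives the model fewer libraries.

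Decay calls depended on the curve shape and on the 9 min libraries. Without the latter 30 genes differed over the 3 stages, 7 between stalked and swarmer, 0 between predivisional and stalked (DESeq2 with all libraries 719) and 50 between predivisional and swarmer cells, and 407 differed in level between predivisional and stalked cells. Straight decay lines gave 0 genes in each of the 4 decay comparisons by edgeR. Between stalked and swarmer, predivisional and stalked, and predivisional and swarmer cells, 788, 549 and 127 genes had an unadjusted p under 0.05. For level these pairs gave 86, 24 and 150 genes. The median slope differences of all genes stayed near the main ones, at -0.204, 0.155 and -0.044 against -0.191, 0.137 and -0.051. Without the 9 min libraries they were 0.039, -0.015 and 0.041. Other tools called more for decay over the 3 stages, with 1385 by DESeq2 with tRNA scaling and 1610, 1462 and 1359 by limma with 0.1 added, with 1 added and without the trend. Between predivisional and stalked cells DESeq2 called 719 with its own scaling and 825 with tRNA scaling, and limma 1141, 946 and 819. Between predivisional and swarmer cells the numbers were 359 and 345 by DESeq2, 26 by limma without the trend, 176 with median-scaled libraries and 73 without the abundance trend. Between stalked and swarmer cells median scaling gave 606 and TMM 579. For level, DESeq2 size factors gave 328 between predivisional and stalked cells.

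With 1 library left out in turn, counts for decay ran from 100 to 1299 over the 3 stages, from 0 to 1442 between stalked and swarmer, from 0 to 874 between predivisional and stalked and from 0 to 280 between predivisional and swarmer cells. Counts for level ran from 444 to 897, from 80 to 313 and from 538 to 1322. Median half-lives ran from 1.14 to 5.65 min in swarmer, from 1.24 to 2.31 min in stalked and from 1.24 to 4.08 min in predivisional cells. Over 0 to 3 min they were 1.14, 1.24 and 1.24 min, over 1 to 9 min 5.65, 2.31 and 4.08 min, and by an exponential fit on the linear scale 0.940, 1.15 and 1.41 min.

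Genes 2-fold rather than 4-fold apart at 0 min numbered 1068 between stalked and swarmer, 526 between predivisional and stalked and 1009 between predivisional and swarmer cells, and with 5 added to RPKM the first 2 comparisons gave 227 and 112 at 4-fold. Spearman's rho of half-life against level was -0.26, -0.26 and -0.22 over 0 to 3 min in swarmer, stalked and predivisional cells, -0.42 in swarmer cells with the level of another stage, and -0.17 and -0.61 in stalked cells with 0.1 and 5 added.

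Of 42 list tests for decay, 11 passed with the preset correlation, 0 with an estimated correlation, 18 by fry and 6 without the 9 min libraries, and 7 to 12 with 1 library left out. For level 19 passed, 1 with an estimated correlation and 16 to 19 with 1 library left out.

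The following decay results took another direction, and some medians of level turned with the scaling or without the 9 min libraries. Between stalked and swarmer cells the slope of CCNA_01924 was 0.83 without the 9 min libraries and ran from -1.52 to 0.44 with 1 library left out, and that of pnp was 0.19 and ran from -0.29 to 0.10. The slope of divJ, -0.01 with adjusted p = 0.876 by edgeR with tRNA scaling, was 0.20 by DESeq2 (adjusted p = 0.00348), 0.19 with TMM (0.0436) and 0.19 with median-scaled libraries (0.0335), so that calls were gained, and that of rhlB, -0.18 with adjusted p = 0.0366 there, was not called at 0.021, 0.013 and 0.009. The flagellum list between stalked and swarmer cells had the direction of its own negative median with fry, which tests against no change (adjusted p = 0.148) and also differed in direction from camera for lists of decay and level that had not passed. Relative to other genes it turned without the 9 min libraries (0.704) and without swarmer 9 min (0.347), with adjusted p from 0.00409 to 0.483 over the left-out libraries, and the chemotaxis list between predivisional and stalked cells without the 9 min libraries (0.498) and without stalked 9 min (0.564), with 9.14e-06 to 0.684 over the left-out libraries. Of 215 called results of named genes, straight decay lines ended 153, leaving out the 9 min libraries ended 41 and reversed 2, and the absence of a level filter ended none. Leaving out 1 library ended 4 to 67, with 67 without swarmer 1 min, 65 without stalked 1 min, 57 without predivisional 1 min, 53 without stalked 0 min and 51 without predivisional 0 min. TMM ended 16 and DESeq2 size factors 10, and each reversed 1.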

Other observations

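The gene groups by shared symbol, the test of gene length at a given RPKM and the tests of genes higher at 9 than at 3 min were chosen after the data were seen; the tests of gene length and of neighbouring genes were written before their results. Some groups of respiratory oxidase genes differed in level from swarmer cells, and stage cannot be told apart here from time since synchrony. All 4 genes with symbols starting cco, which make the cbb3 oxidase, were lower in stalked than in swarmer cells, with a median of -4.28 log2 (adjusted p = 9.22e-06 by camera, and adjusted p = 0.292 with an estimated correlation). The same held for all 4 cyd genes of the bd oxidase and its assembly (-3.35, adjusted p = 5.08e-10, and 0.119 with an estimated correlation) and for 6 of 7 fix genes, several of which act in the response to low oxygen (-2.62, adjusted p = 0.00102, and 0.426 with an estimated correlation). In the other direction 10 of 14 nuo genes of complex I were higher (1.80, adjusted p = 7.75e-06, and 0.399 with an estimated correlation). Between predivisional and swarmer cells the medians were -3.78 for cco (4 of 4 lower), -3.06 for cyd (4 of 4), -1.90 for fix (4 of 7) and 1.85 for nuo (10 of 14 higher). With an estimated correlation adjusted p for these 4 was 0.286, 0.119, 0.419 and 0.618. These directions were the same under each scaling run. The oxidase groups cox and qox did not pass between stalked and swarmer cells (adjusted p = 0.659 for each), and between predivisional and stalked cells no cco or cyd gene was called. There were 45 such groups and 135 tests.

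All 5 cdz genes, which encode a bacteriocin system for killing by contact, were higher in stalked than in swarmer cells (median 2.43, adjusted p = 2.14e-06 by camera, and adjusted p = 0.132 with an estimated correlation). They were higher too in predivisional than in swarmer cells (3.39, adjusted p = 1.58e-08, and adjusted p = 0.119 with an estimated correlation), with the same direction under each scaling run. From stalked to predivisional cells 11 of 13 cpa genes (median 4.90) and all 5 flb genes (5.10), which act in flagellar assembly and its control, rose, with adjusted p of 4.43e-37 and 7.87e-14 and adjusted p = 0.119 with an estimated correlation for both, and with the same direction under each scaling run.

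In swarmer cells 486 genes were at least 2-fold higher at 9 than at 3 min of rifampicin, against 182 in predivisional and 0 in stalked cells. Swarmer and predivisional cells shared 100 of them, where lists drawn independently from all genes tested would share 23.3. Only genes with a scaled count of at least 50 could be listed, and the median at 9 min was 34.0 in swarmer and 31.7 in predivisional cells. The 23.3 leaves out this shared filter, so it is too low a number to judge the overlap by. An overlap expected among the genes that could be listed was not computed. Genomic DNA in the swarmer 9 min library would add reads evenly per kilobase. In the 486 genes the gain per kilobase had a ratio of the 90th to the 10th percentile of 20.4 (729 to 35.7). This argues against DNA as the only source of their gain. A smaller even background from DNA, in these or the other genes, was not tested. Reads of the predivisional 9 min library would not exceed their own source, but 44.9% of the genes, 218 of 486, gained more than their whole predivisional level. This argues against that library as the only source too. Across genes the 9 min profiles of swarmer and predivisional cells had a Spearman's rho of 0.866, against 0.55 and 0.552 for swarmer and predivisional with stalked cells. The stalked 9 min library had a median of 7 reads per gene, against 33 in swarmer and 63 in predivisional cells. The lower values may therefore come from few reads. What raised these reads stays open, and no biological explanation was tested.

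Polymerases that had already started when rifampicin was added could finish their transcripts, so that longer genes would keep more reads at 1 min. Spearman's rho of coding length with the share of reads left at 1 min was 0.28 in swarmer, 0.354 in stalked and 0.323 in predivisional cells, so the lowest of the 3 stages was 0.28. At a given RPKM rho was 0.262, 0.358 and 0.308, and with the share left from 1 to 3 min it was 0.012, 0.022 and 0.012. The relation in the first minute alone is in line with run-off of polymerases, and genes are not independent replicates.

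Neighbouring genes read as 1 transcript might lose reads together. Spearman's rho between neighbours of the share left at 1 min was 0.213, 0.187 and 0.152 in swarmer, stalked and predivisional cells over 2996, 1674 and 3004 pairs, the lowest being 0.152, and the highest of 100 shuffles was 0.04, 0.05 and 0.055. The values lie above those of the shuffles, but in stalked and predivisional cells below the 0.2 that was set beforehand for the lowest stage. Pairs followed gene order without regard to strand, so they can include genes on opposite strands, which are not read as 1 transcript. The gene table also gives no transcript ends. Shared transcripts and other shared properties of neighbours therefore cannot be told apart by these values.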
